A study of Rattus norvegicus with 12 samples.

How the data were processed

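RNA sequencing of 12 rat libraries in 4 groups of 3 replicates was analysed, with BMSC-CT compared with BMSC-C and BF-D with BF-C. Per the labels, the cells came from bone marrow and grew in chondrogenic induction medium, RNA was taken with RNeasy and libraries were made with a NEBNext Ultra kit. Per the submitters' processing notes, Bowtie 0.12.2 and mm8 were used. The notes do not say how reads were assigned to genes, mm8 is a mouse build and the gene IDs are rat Ensembl IDs, so the rat build is unknown and no coordinates are printed.

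The authors deposited 1 gene table per comparison, with 18616 and 19355 genes, of which 17571 are in both. The signal values are normalized counts: per the file headers the authors give 1 value per gene and library, and the deposited values are whole reads divided by 1 size factor per library. Within a tolerance of 0.01, 100% of values were whole multiples of the smallest value of their library, so the reads could be recovered. The authors' log2 fold changes and p-values stand beside them as deposited. DESeq2 on the recovered reads gave the authors' deposited p-value in 100% of 18593 genes and 100% of 19330 genes, to within 0.01 on a log10 scale. Gene lengths, and the other counts of genes per GO and KEGG term, were taken as deposited, and the authors do not name the enrichment tool or its background. The authors' KEGG terms for BF-D cover 149 genes, of which 25 have an adjusted p under 0.05, and the highest unadjusted p among them is 0.0493. The deposited lists of protein interaction pairs hold no measurement of these samples and were not used. All 12 libraries were used, and 0 columns of values were left without a sample. No symbol is given for 904 IDs of the BMSC table and 745 of the BF table, and these IDs took between 0.641% and 1.55% of reads in each library; they were tested but are not named.

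Depth ran from 15580310 to 19870047 reads per library, and 1 read was worth 0.813 to 1.61 normalized counts. The design foresaw a count test for raw reads and limma for normalized values. Because the unit is normalized counts, the main test was limma 3.58.1 (empirical Bayes with a trend) in R 4.3.3. It was run on log2(normalized count + 1) of genes with a mean of at least 1. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Count tests on the recovered reads were run beside it: edgeR 4.0.16 called 3206 and 0 genes in the 2 comparisons, DESeq2 1.42.0 called 5437 and 70, and limma-voom 3239 and 0. With 3 against 3 libraries an exact permutation test cannot give a p under 0.1, so the moderated test was used.

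Before any value was seen, 22 gene lists with 373 members were fixed, for cartilage, bone, fibrous matrix, tendon, contractile, TGF-beta, microtubule, cell cycle, stress, inflammatory, metabolic and cell type genes. Of these, 354 and 358 were found in the tables, and 347 and 352 were tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, and adjusted over the 22 lists. At the preset correlation camera counts degrees of freedom over genes. With an estimated one it uses the few left by the libraries, so fewer lists can pass. Genes were named by a rule fixed before the values were seen. It takes up to 10 rises and 10 falls per comparison that are largest among called genes with separate groups, an above-median mean and a gene symbol. It adds up to 4 members per list with the smallest adjusted p, and Ctgf, Tgfb1, Sparc, Vipr2, Acan, Col2a1, Col1a1 and Acta2. A gene named outside this rule is marked as such. Fold changes against a group without reads use a floor of 3 reads.

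The procedure was tested on simulated data with the spread of each comparison. Of 13657 genes simulated for BMSC-CT, 0 of 67 changed 2-fold, 20 of 67 changed 4-fold and 55 of 66 changed 16-fold were called, with 8 false calls. Of 13576 simulated for BF-D, 41 of 67, 60 of 67 and 66 of 66 were called, with 10 false calls. Of 99 unchanged gene lists, 3 and 6 had a camera p under 0.05. Without BMSC-CT replicate 3, 41.8% of the 2-fold and 85.1% of the 4-fold changes were called, and without BF-D replicate 2 85.1% and 91.0%, with 16 false calls each. In the latter case 11 of 99 unchanged lists passed. Genes were simulated independently of each other, so these counts do not show how camera treats lists of correlated genes. A step that removes the trend of each library with gene length was also tested on simulated data, where it took the Spearman rho with length from -0.512 to -0.00517 and from -0.780 to -0.00594, with 0 false calls by limma before and after.

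Alternatives covered quantile, total-read and TMM scaling, other filters and pseudocounts, a fold threshold, robust variance estimates, a replicate block, each library left out in turn, quality weights per library, removal of the length trend and the tools named above. The effect of docetaxel on genes moved by CTGF and TGF-beta1 was tested with camera and an estimated correlation, and overlaps of called genes with Fisher's exact test, adjusted over 4 tests.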

Results

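RNA from rat bone marrow mesenchymal stem cells (BMSCs) held in chondrogenic induction medium was sequenced in 12 libraries, which fall into 4 groups of 3 replicates. BMSC-C was the control, and BMSC-CT received connective tissue growth factor (CTGF) for 1 week and then TGF-beta1, both matrix-inducing signals. BF-C and BF-D are taken from the series design as induced fibrotic chondrocytes without and with docetaxel, a drug that stabilizes microtubules. The labels state neither the docetaxel dose and time nor how the BF cells were made. They do not say whether replicates were separate cultures, so each p of a single gene measures only the spread between these libraries. The p of overlaps and of the authors' pathway terms count genes instead, and camera sets a list against all other genes. The deposited tables held between 15580310 and 19870047 reads per library.

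Macrophage transcripts were abundant in both BMSC groups and close to absent in both BF groups. The macrophage genes of a fixed list took 0.995 ± 0.104% of reads in BMSC-C, 1.33 ± 0.142% in BMSC-CT, 0.00456 ± 0.000119% in BF-C and 0.00656 ± 0.000337% in BF-D (mean ± SD, n = 3). Lyz2, a lysozyme of macrophages, made up 0.407 ± 0.0413% of reads in BMSC-C and 0.000269 ± 2.53e-05% in BF-C. Its mean in BMSC-CT was 0.810%, most of the share of the list there. Adgre1, a list member chosen after its values were seen, went from a mean of 0.314% in BMSC-C to 0.0963% in BMSC-CT. The higher list share in BMSC-CT therefore does not show that the macrophage genes rose together. Col1a1, the main chain of type I collagen, was higher in BF-C than in either BMSC group, at 4.69 ± 0.0517%. It took 0.164 ± 0.0190% in BMSC-C and 0.661 ± 0.202% in BMSC-CT. These shares of reads were not tested between the BMSC and BF groups. The labels do not say how the BF cells were made, so BF-C is not treated here as a repeat of BMSC-CT.

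Among the libraries, 1 in each treated group stood apart. BMSC-CT replicate 3 had reads in 14621 genes against 16100 or more in the other BMSC libraries, and ribosomal protein genes took 13.7% of its reads against at most 5.93%. Its log2 values correlated with those of replicates 1 and 2 across genes at 0.878 and 0.895, while replicates 1 and 2 correlated at 0.977. BF-D replicate 2 spent 2.64% of its reads on ribosomal protein genes against at most 1.70% in the other BF libraries, and it correlated with replicates 1 and 3 at 0.969 and 0.965. Short genes read high and long genes low in both libraries, with a Spearman rho across genes between deviation and gene length of -0.404 in BMSC-CT replicate 3 and -0.356 in BF-D replicate 2. For most gene lists, counts without the library in question are therefore given beside those from all 6 libraries.

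**Figure D1:**
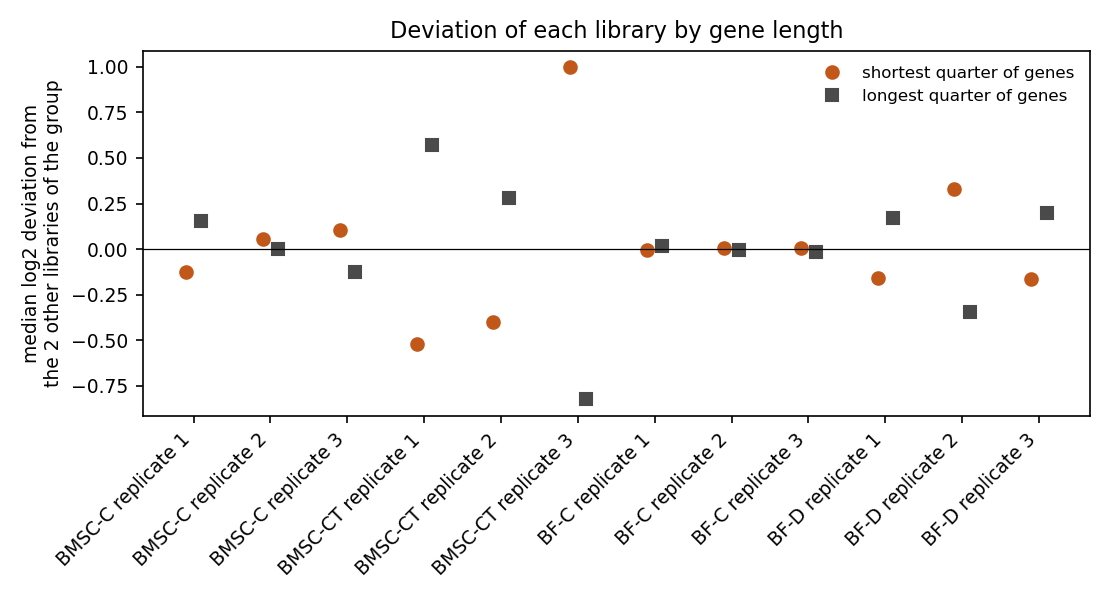
Median log2 deviation of each library from the 2 other libraries of its group, for the shortest and the longest 25% of genes. BMSC-CT replicate 3 lay 1.00 above its group for short genes and 0.82 below it for long genes (median -0.82). BF-D replicate 2 lay at 0.33 and -0.35, while the BF-C libraries stayed within 0.02 of 0.

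Genes of the fibrous matrix moved in both directions when BMSCs received CTGF and then TGF-beta1, the treatment meant to make them fibrotic. Col1a1 (ENSRNOG00000003897) rose from 24234 ± 2703 normalized counts in BMSC-C to 126170 ± 6370 in BMSC-CT (mean ± SD, n = 3 libraries per group), a log2 fold change of 2.39 (standard error 0.24, limma adjusted p = 0.0020). Fold changes are taken on log2(value + 1), which can understate the change of low genes, or overstate it where a single library has no reads. Col3a1, the fibrillar collagen of scars, rose from 1492 ± 452 to 11525 ± 774, and Sparc, a collagen-binding glycoprotein, from 21673 ± 3261 to 89620 ± 5973 (log2 2.06, limma adjusted p = 0.00327). Lox, the enzyme that crosslinks collagen, fell from 9177 ± 1568 to 174 ± 43.4 (log2 -5.73). The proteoglycan Vcan fell from 4265 ± 1008 to 242 ± 60.0. Ctgf itself stood at 4897 ± 734 and 3838 ± 265 and did not pass (limma adjusted p = 0.234). Of the 25 fibrous matrix genes tested, 6 rose, 8 fell and 11 did not pass, while with the trend of each library with gene length removed 12 rose and 7 fell. Adjusted over the list alone, 8 rose and 9 fell, and without BMSC-CT replicate 3 the counts over all genes were 11 and 9. Camera, which sets a list against all other genes, gave this list an adjusted p of 0.989, with a median log2 fold change of -0.06 and a mean of -0.67. The median was 0.35 without BMSC-CT replicate 3 and 0.72 with the length trend removed, a step chosen after seeing the data.

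Tendon genes split as well, contractile genes leaned down, and few cartilage genes passed. Fmod, a collagen-binding proteoglycan of tendon, rose from 353 ± 32.0 to 5326 ± 384 (log2 3.91, limma adjusted p = 0.000196). Tnmd, a membrane protein of tendon cells, rose from 4.23 ± 2.62 to 221 ± 129, while the early-response factor Egr1 fell from 1284 ± 134 to 191 ± 54.5. Of 10 tendon genes tested 2 rose and 4 fell (3 and 5 adjusted over the list alone), and 2 and 5 over all genes without BMSC-CT replicate 3. The list's median of -0.36 and mean of 0.23 differ in sign. Among contractile genes Tpm1 fell from 5082 ± 468 to 951 ± 47.4 and Cald1 from 8919 ± 2604 to 1135 ± 347. Acta2, the smooth muscle actin of myofibroblasts, stood at 440 ± 121 and 254 ± 116 and did not pass (limma adjusted p = 0.164, and 0.0199 without BMSC-CT replicate 3). Of the 15 contractile genes 1 rose and 5 fell (1 and 6 adjusted over the list alone), and 9 fell without BMSC-CT replicate 3. Camera gave this list an adjusted p of 0.0797, and 0.00548 without BMSC-CT replicate 3, against adjusted p = 0.278 with an estimated correlation. Prg4, the lubricating proteoglycan of joint surfaces, fell from 1812 ± 453 to 255 ± 40.3, and Acan, the main proteoglycan of hyaline cartilage, stood at 3.10 ± 2.18 and 0.301 ± 0.522 (limma adjusted p = 0.122). Of 13 hyaline cartilage genes 2 rose and 1 fell, and of 8 genes of hypertrophic cartilage and bone 2 rose and 1 fell. Adjusted over the list alone the counts were 2 and 1, and 2 and 2, and over all genes without BMSC-CT replicate 3 they were 3 and 1, and 2 and 3. Over all 6 libraries camera gave neither list an adjusted p under 0.753, and without BMSC-CT replicate 3 it gave hyaline cartilage genes 0.654. Col2a1 is not listed in the BMSC table and was not analysed there.

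Many genes of the TGF-beta pathway and many targets of YAP, a factor that responds to cell tension, fell. Bmp2 went from 839 ± 122 to 4.87 ± 4.22 normalized counts, and Bmp4 from 480 ± 38.8 to 9.68 ± 8.75. Ltbp2, a binding protein for latent TGF-beta, fell from 14309 ± 691 to 2944 ± 212 (log2 -2.28, limma adjusted p = 0.000945), and Grem1, an inhibitor of BMPs, from 46794 ± 8884 to 181 ± 49.8 (log2 -8.02). Tgfb1 stood at 6181 ± 1499 and 11094 ± 3657 and did not pass (limma adjusted p = 0.104). Of 26 TGF-beta pathway genes 1 rose and 10 fell, 1 and 12 adjusted over the list alone, and 2 and 15 over all genes without BMSC-CT replicate 3. Camera gave an adjusted p of 0.00245 and adjusted p = 0.585 with an estimated correlation. Cyr61, a matricellular YAP target, fell from 7615 ± 601 to 145 ± 11.8 (log2 -5.70, limma adjusted p = 0.000165), Amotl2 from 4833 ± 213 to 911 ± 305 and Ajuba from 1230 ± 231 to 246 ± 62.1. Of 15 YAP targets 7 fell, 9 adjusted over the list alone, and 0 rose by limma, edgeR or DESeq2, with 0 also higher at an unadjusted p under 0.05. Over all genes 9 fell without BMSC-CT replicate 3. Their median was -2.04, with camera adjusted p = 0.000213 and adjusted p = 0.585 with an estimated correlation.

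Many cytokine and matrix protease genes fell in the same cells. Il11, an IL-6 family cytokine, fell from 12644 ± 2132 to 12.9 ± 7.27 (log2 -9.95, limma adjusted p = 0.000165). Il6 fell from 4918 ± 505 to 23.8 ± 11.1 and Ptgs2, the inducible cyclooxygenase, from 20703 ± 5584 to 186 ± 114. The chemokine Cxcl2, which may share reads with its paralog Cxcl1, fell from 7773 ± 2370 to 218 ± 35.4. Of 21 inflammatory genes 1 rose and 9 fell, with the same counts adjusted over the list alone, and 1 and 11 over all genes without BMSC-CT replicate 3. Camera gave an adjusted p of 0.00262, against adjusted p = 0.348 with an estimated correlation. The stromelysin Mmp3, which may share reads with Mmp10, fell from 119160 ± 28406 to 8543 ± 1188, the gelatinase Mmp9 from 33215 ± 10135 to 2696 ± 761 and Mmp12 from 32870 ± 2975 to 6544 ± 885. Of 16 matrix protease genes 1 rose and 7 fell, 4 and 8 adjusted over the list alone, and 4 and 8 over all genes without BMSC-CT replicate 3. Their median was -2.07 and camera gave 0.0797, against -1.12 and 0.181 without BMSC-CT replicate 3. Esm1, a secreted proteoglycan, fell from 7944 ± 944 to 9.54 ± 5.77, and Mstn, which restrains muscle growth, from 625 ± 137 to 0 reads in every BMSC-CT library, at least 525-fold lower with a floor of 3 reads over the group.

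Most genes of the unfolded protein response rose, and several of hypoxia and glycolysis fell. Hspa5, the main chaperone of the endoplasmic reticulum, rose from 16307 ± 2322 to 86659 ± 4925 (log2 2.42, limma adjusted p = 0.00181). Herpud1, which helps to degrade misfolded protein there, rose from 2629 ± 139 to 15419 ± 2418, and the folding enzyme Pdia4 from 4514 ± 871 to 16957 ± 2358. Asns, the asparagine synthetase of the amino acid response, fell from 5035 ± 487 to 1612 ± 182. Of 15 genes on this list 10 rose and 2 fell, with the same counts adjusted over the list alone, and 12 and 2 over all genes without BMSC-CT replicate 3. Their median was 1.83 with camera adjusted p = 0.000213, against adjusted p = 0.348 with an estimated correlation. Adm, a vasodilator peptide induced by low oxygen, fell from 6275 ± 504 to 100 ± 7.12, and Car9 from 190 ± 15.4 to 21.5 ± 4.08. Of 15 hypoxia and glycolysis genes 7 fell (9 adjusted over the list alone). By limma, edgeR and DESeq2 0 rose, with 0 higher at an unadjusted p under 0.05, although 1 rose and 10 fell in limma without BMSC-CT replicate 3. Camera gave that list an adjusted p of 0.00245, and adjusted p = 0.348 with an estimated correlation. The stress gene Gadd45a rose from 1499 ± 225 to 9113 ± 2036 and the death receptor Fas from 142 ± 15.4 to 526 ± 39.6. Of 18 p53 targets 6 rose and 1 fell, 7 and 1 adjusted over the list alone, and 10 and 1 over all genes without BMSC-CT replicate 3, with camera adjusted p = 0.0114 and adjusted p = 0.348 with an estimated correlation. Insig1, a brake on sterol synthesis, rose from 1809 ± 27.9 to 6854 ± 1255, and of 15 cholesterol synthesis genes 4 rose and 1 fell, also when adjusted over the list alone. Over all genes 7 rose and 1 fell without BMSC-CT replicate 3, and 6 and 1 with the length trend removed. Camera gave that list 0.0612, and 0.0059 without BMSC-CT replicate 3 against adjusted p = 0.406 with an estimated correlation. Its median of 0.34 was -0.08 when libraries were scaled to total reads and 0.92 with the length trend removed.

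Genes of macrophages rose and fell, and most genes of mesenchymal stem cells stood lower. Csf1r, the receptor that macrophages need to live, rose from 773 ± 63.3 to 3371 ± 430 (log2 2.12, limma adjusted p = 0.0015), and Lyz2 from 60048 ± 7917 to 160790 ± 31039 (limma adjusted p = 0.0224). The call of Lyz2 was lost without BMSC-C replicates 1, 2 and 3 and BMSC-CT replicate 2 (0.131, 0.134, 0.0769 and 0.0829). Cd74, a chaperone of antigen presentation, fell from 1045 ± 226 to 170 ± 122 (limma adjusted p = 0.0131, and 0.0708, 0.0623 and 0.0616 without BMSC-C replicates 1, 2 and 3). Adgre1, a surface receptor of macrophages named after its values were seen, fell from 46426 ± 5183 to 17359 ± 6492 (limma adjusted p = 0.0334). Its adjusted p was 0.132, 0.119, 0.112 and 0.0640 without BMSC-C replicates 1, 2 and 3 and BMSC-CT replicate 2, and 0.00550 without BMSC-CT replicate 3. Of 17 macrophage genes 6 rose and 2 fell, 8 and 6 adjusted over the list alone, and 8 and 8 over all genes without BMSC-CT replicate 3. Their median was -0.41 (0.28 without BMSC-CT replicate 3) and their mean -0.08, while camera pointed up with an adjusted p of 0.556. Pmel and Mlana, melanosome genes, were among the largest rises, Pmel from 39.9 ± 5.89 to 2616 ± 368 and Mlana from 1.08 ± 1.88 to 1084 ± 819. Cxcl12, a chemokine of marrow stroma, fell from 3474 ± 226 to 27.6 ± 9.62 and Pdgfra, a growth factor receptor of mesenchymal cells, from 14851 ± 1441 to 1885 ± 953. Of 10 mesenchymal stem cell genes 1 rose and 3 fell, 1 and 5 adjusted over the list alone, and 1 and 5 over all genes without BMSC-CT replicate 3; 2 of the 10 were higher, the median was -1.10 (-0.67 without BMSC-CT replicate 3 and -0.63 with the length trend removed), and camera gave 0.0696. Of 8 adipocyte genes 1 rose and 1 fell (2 and 1 adjusted over the list alone), Lpl falling from 7952 ± 1890 to 745 ± 152, and of 6 endothelial genes 1 rose and 1 fell (1 and 2 adjusted over the list alone). Over all genes without BMSC-CT replicate 3 the counts were 3 and 1, and 1 and 2, and camera gave both lists 0.399.

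Few microtubule genes passed in this comparison. Stmn1, which destabilizes microtubules, rose from 245 ± 51.6 to 2021 ± 1262 (limma adjusted p = 0.00815), and the kinase Dclk1, which binds them, fell from 727 ± 125 to 102 ± 28.7. Tubb2a and Tubb2b, near-identical tubulins whose reads can be shared, rose from 320 ± 67.7 to 791 ± 216 and from 19.1 ± 3.0 to 70.1 ± 12.2. Both calls were lost without BMSC-C replicates 1, 2 and 3 and BMSC-CT replicate 2, Tubb2a at limma adjusted p of 0.116, 0.123, 0.0545 and 0.0799 and Tubb2b at 0.0919, 0.104, 0.0590 and 0.0744. Of 16 tubulins 2 rose, also when adjusted over the list alone, and 4 over all genes without BMSC-CT replicate 3. On that list edgeR called 2 higher and DESeq2 5, with 5 higher at an unadjusted limma p under 0.05. By limma, edgeR and DESeq2 0 fell, with 0 lower at an unadjusted p under 0.05. Their median was 0.61 (0.13 without BMSC-CT replicate 3). Camera gave 0.0797, with 0.319 without BMSC-CT replicate 3, 0.215 with the length trend removed, and 0.0493 without BMSC-CT replicate 1, where no correlation was estimated. Of 22 microtubule-associated genes 1 rose and 2 fell (2 and 3 adjusted over the list alone), and 3 and 8 over all genes without BMSC-CT replicate 3, with camera at 0.399. Of 20 mitosis genes 0 rose and 0 fell by limma, also when adjusted over the list alone, with 1 higher and 2 lower at an unadjusted p under 0.05. On that list edgeR called 1 lower, DESeq2 1 higher and 1 lower, and limma 1 higher and 3 lower without BMSC-CT replicate 3; camera gave 0.989. Of 17 DNA replication genes 1 rose and 1 fell, and of 19 interferon response genes 4 rose and 1 fell. Adjusted over the list alone the counts were 1 and 1, and 6 and 2, with camera at 0.645 and 0.360, and over all genes without BMSC-CT replicate 3 they were 2 and 4, and 6 and 3. The small RNA 7SK and a 5.8S ribosomal RNA were also among the largest rises, at 2430 ± 2746 and 2114 ± 2570 in BMSC-CT, with an SD above the mean; the call of the latter was lost without BMSC-C replicates 1 and 2 (limma adjusted p = 0.0631 and 0.0616). Vipr2, a receptor for a neuropeptide, fell from 66.3 ± 10.2 to 21.0 ± 11.2 at a limma adjusted p of 0.0461. Without BMSC-C replicates 1, 2 and 3 and BMSC-CT replicate 1 it was 0.175, 0.174, 0.110 and 0.0767.

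**Figure D2:**
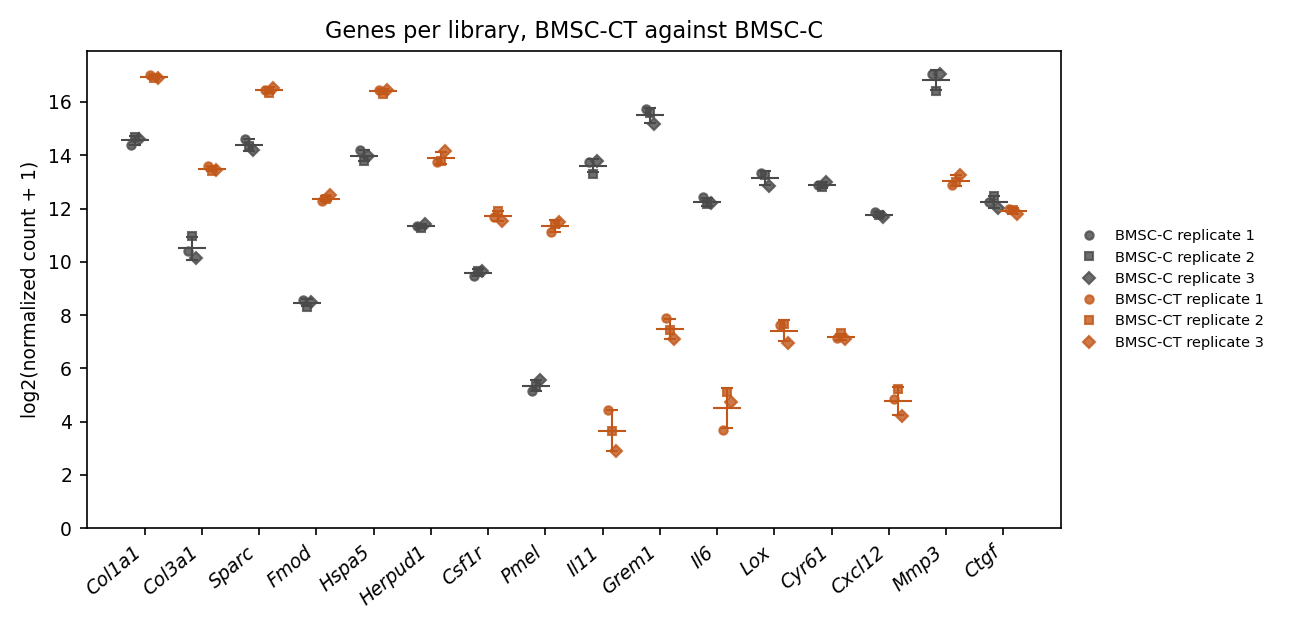
Log2(normalized count + 1) of 16 genes in each BMSC-C and BMSC-CT library (points), with the mean and SD of each group (bars, n = 3). Col1a1, Col3a1, Sparc, Fmod, Hspa5, Herpud1, Csf1r and Pmel rose, Il11, Grem1, Il6, Lox, Cyr61, Cxcl12 and Mmp3 fell, and Ctgf did not pass the test.

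Across all 16818 genes tested, 1295 rose and 1839 fell (limma, adjusted p under 0.05), 6489 passing unadjusted. By its adjusted p the authors' deposited table has 2695 higher and 2702 lower, and edgeR on the recovered reads called 1533 and 1673. The count depended on single libraries: 6797 without BMSC-CT replicate 3, and 816, 744, 1263 and 1221 without BMSC-C replicates 1, 2 and 3 and BMSC-CT replicate 2. All 3134 genes were also called, in the same direction, without BMSC-CT replicate 3. Of 112 genes that the naming rule picked, 94 passed, and 62 of these passed whichever library was left out. None of the 6 camera calls holds with an estimated correlation. Fry, which tests a list without comparing it to other genes, also passed these 6, and besides them contractile, matrix protease, endothelial, mesenchymal stem cell, DNA replication and cholesterol synthesis genes. Its adjusted p for these were 0.0132, 0.0138, 0.00668, 0.00457, 0.0481 and 0.0159, where inter-gene correlation is allowed for. Correlation alone does not account for every lost camera call, because camera with an estimated correlation also has far fewer degrees of freedom. The estimates for hypoxia and glycolysis and p53 target genes, -0.0517 and -0.0429, lay below the preset 0.01. Their unadjusted camera p still rose, from 0.000337 to 0.0186 and from 0.00311 to 0.0330. The median log2 fold change of all genes was -0.15 with the authors' size factors, 0.08 after quantile normalization and -0.55 when scaled to total reads, so shifts of that size depend on the scaling. In simulated data with this spread, 29.9% of genes changed 4-fold and 83.3% of genes changed 16-fold were called, but 0 of 67 changed 2-fold. The simulation held far fewer changed genes than the 3134 called here, which makes an adjusted p under 0.05 harder to reach. These shares may therefore be too low. Of the 3134 called genes 2854 had an absolute log2 fold change of at least 1, so some smaller changes were called. Genes that did not pass may still have changed 2-fold.

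The pathway terms in the authors' deposited table cover lysosome and cytokine genes. For BMSC-CT the authors list Lysosome with 69 genes, 64 of them higher (adjusted p = 0.000268), Phagosome with 54 of 81 higher, and Cytokine-cytokine receptor interaction with 67 of 94 lower. Among lysosomal and macrophage genes chosen here after their values were seen, Ctsd, a lysosomal protease, rose from 46703 ± 10654 to 195520 ± 87230 (limma adjusted p = 0.0206). Lamp1, a lysosomal membrane protein, rose from 17027 ± 306 to 40962 ± 3620 (0.0108), and Ctsk, a collagen-degrading protease of osteoclasts, from 1548 ± 111 to 5048 ± 1775 (0.0109). Without BMSC-C replicates 1, 2 and 3 the limma adjusted p were 0.116, 0.106 and 0.0654 for Ctsd, 0.0757, 0.0856 and 0.0558 for Lamp1, and 0.0669, 0.0620 and 0.0516 for Ctsk. Without BMSC-CT replicate 2 those of Ctsd and Lamp1 were 0.0677 and 0.0527. Also chosen after their values were seen are Gas6 and Srebf1. The ligand Gas6 rose from 1698 ± 258 to 36163 ± 6544, while Axl, a receptor it binds, fell from 11139 ± 428 to 3552 ± 581. Srebf1, a regulator of lipid synthesis, rose from 930 ± 205 to 27998 ± 3714.

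With docetaxel, Spp1 rose in the BF cells and all but 1 other gene stayed short of the threshold. The comparison of BF-D with BF-C asks what the drug does to induced fibrotic chondrocytes. Spp1 (ENSRNOG00000043451), or osteopontin, a phosphoprotein of bone and of inflamed tissue, rose from 1175 ± 68.5 normalized counts in BF-C to 2687 ± 320 in BF-D (mean ± SD, n = 3), a log2 fold change of 1.19 (standard error 0.11, limma adjusted p = 0.0427). The only other gene past the threshold was AABR07052758.1 (ENSRNOG00000059883), a long noncoding RNA outside the naming rule and named after its values were seen, which fell from 404 ± 82.9 to 35.5 ± 13.7 (log2 -3.53, limma adjusted p = 0.0427). Spp1 had also risen with CTGF and TGF-beta1, from 6819 ± 557 in BMSC-C to 14609 ± 702 in BMSC-CT (limma adjusted p = 0.0119). That call was lost without BMSC-C replicates 1, 2 and 3 and BMSC-CT replicate 2 (0.0657, 0.0909, 0.0529 and 0.0563). In BF-D the limma adjusted p of Spp1 was 0.362, 0.443 and 0.358 without BF-C replicates 1, 2 and 3, and 0.111, 1.93e-05 and 0.216 without BF-D replicates 1, 2 and 3. That of AABR07052758.1 was 0.362, 0.199 and 0.358, and 0.0579, 4.55e-05 and 0.216. By edgeR on the recovered reads both stood at an adjusted p of 0.0579.

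Across the 17076 genes tested, limma called 1 higher and 1 lower, with 1058 at an unadjusted p under 0.05. DESeq2 on the recovered reads, like the authors' deposited table, gave 37 higher and 33 lower, while edgeR and limma-voom gave 0, with 885 and 910 genes at an unadjusted p under 0.05. Without BF-D replicate 2 limma called 115 higher and 130 lower, and leaving out any other library gave 0 or 1. Of 94 genes that the naming rule picked, 0 passed whichever library was left out. A further 32 passed only with a library left out, in each case BF-D replicate 2. That library was singled out because it stood apart in these same data, so p-values without it may be too small. Removing the trend of each library with gene length, a step chosen after seeing the data, gave 7 higher (among them Spp1, Mmp12, Cxcl2, Mmp9 and Ptgs2) and 4 lower. In simulated data with this spread, 61.2% of genes changed 2-fold and 89.6% of genes changed 4-fold were called. The simulation held many more changed genes than the 2 called here, which makes an adjusted p under 0.05 easier to reach. These shares may therefore be too high for this comparison. Il1b, for example, stood at 12.4 ± 3.10 and 45.5 ± 9.11 (log2 1.80) with a limma adjusted p of 0.318.

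Several metalloproteinases and many inflammatory genes stood higher with docetaxel without passing over all 6 libraries. Mmp9 went from 71246 ± 1321 to 107960 ± 3538 (log2 0.60, limma adjusted p = 0.231), Mmp13, the collagenase of cartilage breakdown, from 12952 ± 546 to 19729 ± 1601 (0.231) and Mmp12 from 236 ± 16.9 to 477 ± 77.6 (0.23). Without BF-D replicate 2 the limma adjusted p were 2.04e-05, 7.26e-05 and 0.00135. None of these genes passed with any other library left out, and without BF-C replicate 1 each stood at 0.917. Cxcl2 stood at 3154 ± 103 and 5865 ± 1193 and Ptgs2 at 16161 ± 567 and 21536 ± 2484 (limma adjusted p = 0.285 and 0.65, or 2.04e-05 and 7.26e-05 without BF-D replicate 2). Il11, named after its values were seen, stood at 4654 ± 199 and 8468 ± 892 (limma adjusted p = 0.145, and 2.04e-05 without BF-D replicate 2). Of 20 inflammatory genes, 0 passed over all genes by limma or edgeR, against 8 higher and 1 lower at an unadjusted p under 0.05 and 2 higher by DESeq2. On this list 3 were higher adjusted over the list alone, and 6 rose without BF-D replicate 2. Their median was 0.26 (0.11 without BF-D replicate 2), with camera adjusted p = 3.1e-06 and adjusted p = 0.243 with an estimated correlation. Of 16 matrix protease genes 2 were higher adjusted over the list alone, and over all genes 3 rose and 1 fell without BF-D replicate 2. Over all 6 libraries 0 of them passed by limma or edgeR, with 3 higher and 2 lower at an unadjusted p under 0.05, 2 higher by DESeq2 and camera at 0.956. As a list they did not stand higher: 6 of 16 were higher, the median was -0.07 (-0.02 without BF-D replicate 2 and near 0 with the length trend removed), and Adamts5, which cleaves aggrecan, stood at 5937 ± 181 and 3749 ± 1269 (limma adjusted p = 0.706, and 0.000554 without BF-D replicate 2). For BF-D the authors' deposited table lists Cytokine-cytokine receptor interaction with 30 of 37 genes higher (adjusted p = 1.83e-07), of which 11 pass its own adjusted threshold, and IL-17 signaling with 12 of 15 higher.

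Collagens and other fibrous matrix genes stood lower with docetaxel. Col3a1 went from 122080 ± 916 to 96010 ± 2964 (log2 -0.35, limma adjusted p = 0.655), Col1a1 from 786610 ± 11162 to 644520 ± 56449 (0.706) and Sparc from 184680 ± 2298 to 157590 ± 6098 (0.706). Without BF-D replicate 2 all 3 fell, at limma adjusted p of 0.000554, 0.0112 and 0.0107. None of the 3 passed with any other library left out, and without BF-C replicate 1 each stood at 0.917. Of 26 fibrous matrix genes, 0 passed by limma or edgeR, also adjusted over the list alone, with 9 lower at an unadjusted p under 0.05 and 1 lower by DESeq2. Of these genes 8 fell without BF-D replicate 2. Their median was -0.28 (-0.12 both without BF-D replicate 2 and with the length trend removed), with camera adjusted p = 6.67e-07 and adjusted p = 0.328 with an estimated correlation. Acta2 stood at 7135 ± 502 and 10392 ± 3730 (limma adjusted p = 0.706), and Ctgf at 10800 ± 338 and 11459 ± 1596. Of the 15 contractile genes 0 passed by limma, edgeR or DESeq2, also adjusted over the list alone, with 1 higher at an unadjusted p under 0.05. BF-D replicate 2 was the highest library for Acta2 at 14615 against 7546 and 9015 in replicates 1 and 3. Camera gave 0.00315 with a median of 0.33 (0.15 without BF-D replicate 2), and adjusted p = 0.328 with an estimated correlation. Of 10 tendon genes 1, Fmod, was lower adjusted over the list alone, at 7074 ± 43.1 and 5343 ± 522 (limma adjusted p = 0.484 over all genes, and 0.00291 without BF-D replicate 2), with camera at 0.961. Of 17 hyaline cartilage genes 1 was higher and 1 lower adjusted over the list alone, and 1 and 1 over all genes without BF-D replicate 2, with camera at 0.628. Col2a1, the collagen of hyaline cartilage, stood at 2.78 ± 1.26 and 4.78 ± 5.29.

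Tubulins, the proteins that docetaxel binds, stood higher as a list. Tubb3 went from 687 ± 25 to 1028 ± 130 (log2 0.57, limma adjusted p = 0.413), Tuba1a from 4195 ± 178 to 6423 ± 1651 and Tubb5 from 8614 ± 134 to 10780 ± 1082. Without BF-D replicate 2 all 3 rose, at limma adjusted p of 0.00369, 0.00174 and 0.00586. None of the 3 passed with any other library left out, and without BF-C replicate 1 each stood at 0.917. Of 15 tubulins 0 passed over all genes by limma or edgeR, with 10 higher at an unadjusted p under 0.05 and 1 higher by DESeq2. Of the list, 8 were higher adjusted over the list alone and 4 rose without BF-D replicate 2. Their median was 0.36, with camera adjusted p = 4.43e-07 and adjusted p = 0.263 with an estimated correlation. Of 23 microtubule-associated genes 0 passed by limma, edgeR or DESeq2, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.122). Mitosis genes, which a block of cell division would move, had a median of -0.17 over 20 genes. By limma, edgeR and DESeq2 0 passed, also adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 and camera at 0.231.

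Interferon and macrophage genes also stood higher, the latter at low levels. Irf7, a regulator of interferon genes, went from 1580 ± 236 to 2325 ± 265 (limma adjusted p = 0.569, and 0.0417 without BF-D replicate 2). Of 19 interferon response genes 0 passed by limma, edgeR or DESeq2, also adjusted over the list alone, with 9 higher at an unadjusted p under 0.05, and 1 rose without BF-D replicate 2. Their median was 0.42, with camera adjusted p = 1.88e-07 and adjusted p = 0.243 with an estimated correlation. Lyz2 went from 45.1 ± 4.47 to 136 ± 31.3 and Cd68, a lysosomal protein of macrophages, from 103 ± 10.3 to 177 ± 6.18 (limma adjusted p = 0.23 and 0.413, or 0.00605 and 0.0273 without BF-D replicate 2). Of 14 macrophage genes 0 passed by limma or edgeR, with 6 higher at an unadjusted p under 0.05, 2 higher by DESeq2, 6 higher adjusted over the list alone and 2 rising without BF-D replicate 2. Their median was 0.62, with camera adjusted p = 2.33e-06 and adjusted p = 0.243 with an estimated correlation. Camera also passed the hypoxia and glycolysis list (median 0.18, or 0.06 without BF-D replicate 2, 0.00315; 1 higher adjusted over the list alone) and the cholesterol synthesis list (median 0.12, 0.0109), both with adjusted p = 0.328 with an estimated correlation. Over all genes 2 hypoxia and 3 cholesterol genes rose without BF-D replicate 2. The cholesterol call was lost without BF-C replicate 1 and BF-D replicates 1 and 3 (0.0976, 0.201 and 0.0679). None of the 8 camera calls holds with an estimated correlation, where the libraries leave few degrees of freedom. Their loss therefore need not come from correlated genes. Of these 8 lists fry passed only the macrophage genes (adjusted p = 0.0387 with inter-gene correlation allowed for), and inflammatory, interferon, tubulin and fibrous matrix genes stood at 0.0670, 0.0952, 0.101 and 0.154. Fry also passed the hypertrophic cartilage and bone list (adjusted p = 0.0234, against 0.126 by camera at the preset correlation), pointing up although its median was -0.08 and 5 of 11 were higher. The TGF-beta pathway list had 2 members higher adjusted over the list alone, among them Tgfb3 at 911 ± 27.2 and 1344 ± 141 (limma adjusted p = 0.413 over all genes, and 0.00228 without BF-D replicate 2). Camera gave it 0.628, and 0.0176 without BF-D replicate 2, against adjusted p = 0.338 with an estimated correlation. The remaining 8 lists, of hypertrophic cartilage and bone, DNA replication, p53 target, YAP target, adipocyte, endothelial, mesenchymal stem cell and unfolded protein response genes, had camera adjusted p of 0.0789 or more. Hypertrophic cartilage and bone genes reached 0.0212 without BF-D replicate 2 (adjusted p = 0.2003 with an estimated correlation), and unfolded protein response genes 0.0426 without BF-D replicate 3, where no correlation was estimated. Adjusted over the list alone, Spp1, Mmp13 and the p53 target Gdf15 were higher, and the stromal Cxcl12 and the endothelial factor Erg were lower. Gdf15 stood at 1223 ± 74.9 and 2123 ± 496 and Cxcl12 at 29400 ± 378 and 22692 ± 1113 (limma adjusted p over all genes 0.413 and 0.458, or 0.000549 and 0.00118 without BF-D replicate 2).

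**Figure D3:**
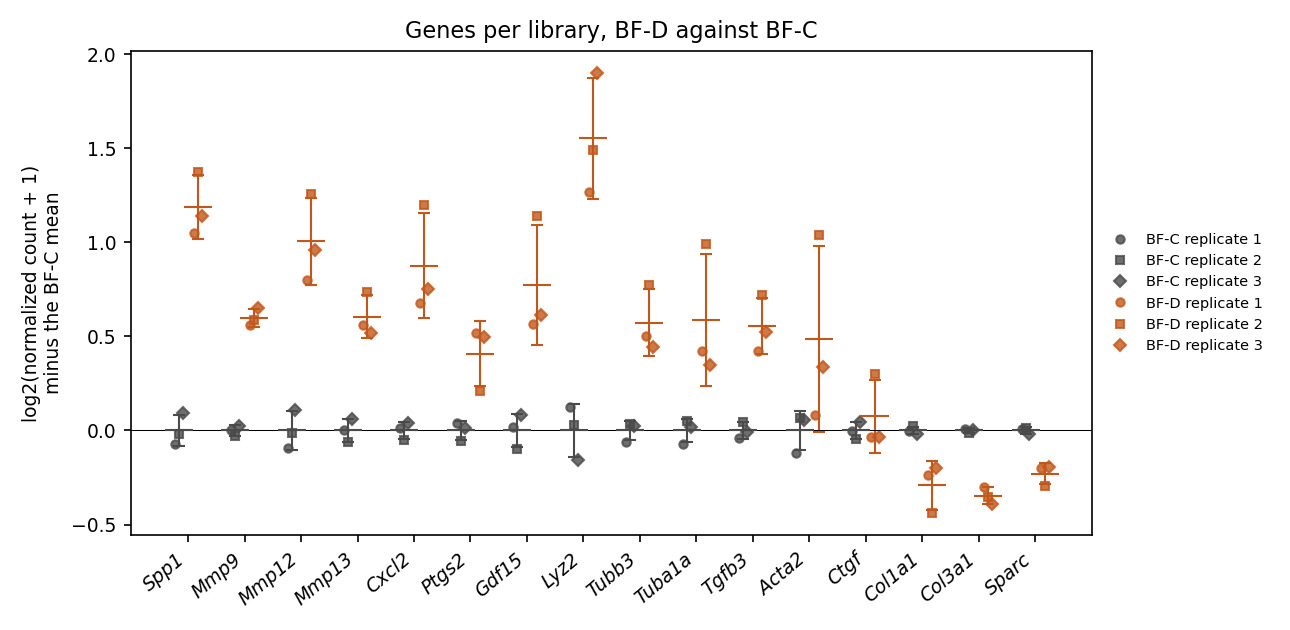
Log2(normalized count + 1) of 16 genes in each BF-C and BF-D library (points), less the mean of BF-C, with the mean and SD of each group (bars, n = 3). Spp1 passed the test over all genes; the other genes shown did not, and BF-D replicate 2 is the highest BF-D library for Spp1, Mmp12, Mmp13, Cxcl2, Gdf15, Tubb3, Tuba1a, Tgfb3, Acta2 and Ctgf.

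**Figure D4:**
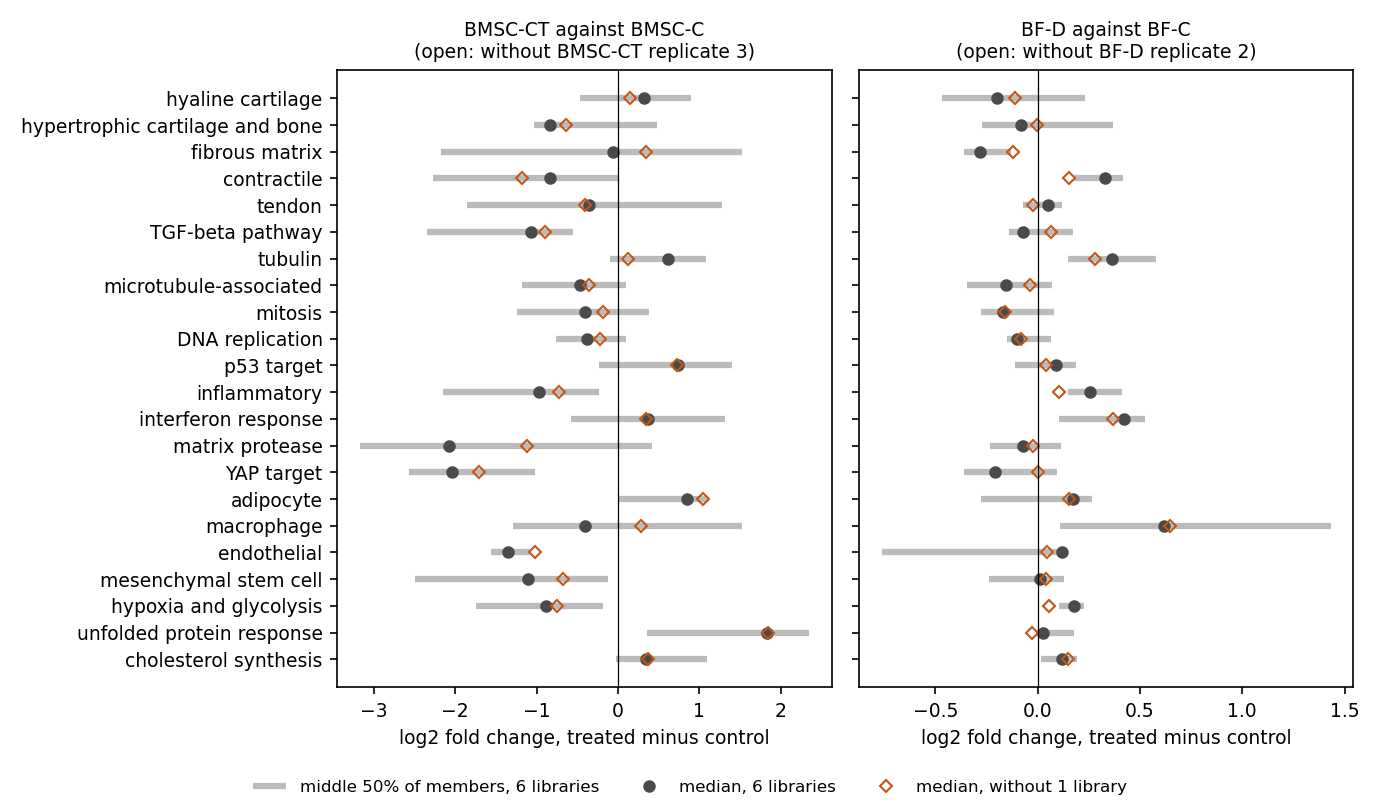
Median log2 fold change of 22 fixed gene lists with the interquartile range of their members (grey), from all 6 libraries (filled) and without the library that stood apart (open). The unfolded protein response list lay at 1.83 and the YAP target list at -2.04 in BMSC-CT, while in BF-D the lists lay between -0.28 and 0.62.

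Whether docetaxel acts on the genes that CTGF and TGF-beta1 moved was tested across both tables. The 1215 genes raised in BMSC-CT and tested in BF had a median log2 fold change of 0.04 with docetaxel, 41.7% of them lower (camera with an estimated correlation, p = 0.369), and the 1751 lowered genes a median of -0.02 (p = 0.996). With the sets drawn without BMSC-C replicate 1 or without BMSC-C replicate 2, the median of raised genes was -0.03 in both cases and that of lowered genes 0.03 and 0.04 (p = 0.0340 and 0.0237 with an estimated correlation). Without BF-D replicate 2 the medians of raised and lowered genes were 0.00 and 0.01, with 49.8% of the raised genes lower and camera pointing down for them (p = 0.857 with an estimated correlation). Over all libraries Spp1, the 1 gene higher with docetaxel, was among the raised genes (Fisher p = 0.0769, adjusted over 4 overlaps 0.307), and the other 3 overlaps held 0 genes (Fisher p = 1). The overlaps that follow leave out BF-D replicate 2, a choice made after seeing the data. Among the 115 genes higher in BF-D, 63 had fallen in BMSC-CT, against 12.7 from chance (Fisher's exact test, p = 1.28e-30, adjusted over 4 overlaps 5.1e-30), and 12 had risen, against 8.84 (Fisher p = 0.288). Mmp9, Cxcl2, Ptgs2 and Il11 fell with CTGF and TGF-beta1, and stood higher with docetaxel. With the length trend removed and all libraries kept, 6 of the 7 genes higher with docetaxel had fallen in BMSC-CT, against 0.775 from chance (Fisher p = 1.16e-05, adjusted 4.65e-05). Of the 130 genes lower in BF-D, 27 had risen in BMSC-CT against 9.99 from chance (Fisher p = 1.64e-06, adjusted 2.19e-06) and 35 had fallen against 14.4 (Fisher p = 6.23e-07, adjusted 1.25e-06). The fold changes of 15806 genes correlated at a Spearman rho of 0.272 over all libraries and 0.0318 without BF-D replicate 2; genes are not independent replicates, and the tables share no library. The chance counts treat all 15806 genes alike, with no background matched for expression level. Genes that are easier to call in both comparisons could raise any overlap. Genes lowered in BMSC-CT were in excess among both the 115 higher and the 130 lower genes. The overlaps therefore do not show that docetaxel reverses the treatment.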

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

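The tests on recovered reads, quality weights, total-read and TMM scaling and removal of the gene length trend were chosen after seeing the data, and the other alternatives were fixed before.

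For BMSC-CT against BMSC-C the 3134 called genes became 5397 with the authors' deposited adjusted p, 5437 with DESeq2, 12357 with quality weights per library, and 7278 with the length trend removed and BMSC-CT replicate 3 left out. The quality weights were 0.310, 19.3 and 0.0601 for BMSC-CT replicates 1, 2 and 3. The weighted count thus rests almost wholly on replicate 2 in the treated group and is not comparable with the others. Leaving out 1 library gave from 744 (BMSC-C replicate 2) to 6797 genes (BMSC-CT replicate 3); BMSC-C replicates 1 and 3 and BMSC-CT replicate 2 gave 816, 1263 and 1221. The share of called genes that rose was 41.3% in the main test, 51.8% after quantile normalization, 28.5% when scaled to total reads and 53.8% with the length trend removed, so the balance of rises and falls depends on the scaling. Camera passed 6 lists, and 0 with an estimated correlation, where degrees of freedom are few. No named gene or list past the threshold changed direction under these alternatives, but medians of lists that did not pass changed sign, such as fibrous matrix (-0.06, and 0.35 without BMSC-CT replicate 3) and macrophage genes (-0.41, and 0.28). The cause of these shifts was not tested beyond gene length.

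For BF-D against BF-C the 2 called genes became 0 with a mean of at least 10 (871 at an unadjusted p under 0.05), with edgeR (885), with edgeR and RLE factors (878) and with limma-voom (910), and 70 with DESeq2 and with the authors' deposited adjusted p. Quality weights gave 125, removal of the length trend 11, and removal of the length trend without BF-D replicate 2 264. Leaving out 1 library gave from 0 to 245 genes, the highest without BF-D replicate 2; without BF-C replicate 1 both calls were lost and 1 other gene passed, and the other 4 gave 0. Camera passed 8 lists, and 0 with an estimated correlation, where degrees of freedom are few. No named gene or list past the threshold changed direction, although the TGF-beta pathway median, not past it over all 6 libraries, turned from -0.07 to 0.07 without BF-D replicate 2.

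The median docetaxel effect on genes raised by CTGF and TGF-beta1, 0.0408, kept that value at the preset correlation of 0.01, where its camera p fell to 0.0399 from 0.369. With 1 library left out it lay between -0.0334 (without BMSC-C replicate 1) and 0.0741 (without BMSC-CT replicate 1). On lowered genes the median of -0.0192 ran from -0.0609 (without BMSC-CT replicate 1) to 0.0444, and it was above 0 without BMSC-C replicate 3 (0.00725), without BF-D replicate 2 (0.0111), without BMSC-C replicate 1 (0.0278, camera p = 0.0340 with an estimated correlation) and without BMSC-C replicate 2 (0.0444, camera p = 0.0237 with an estimated correlation). With the length trend removed the medians were 0.0398 and 0.0293. The cause was not tested.

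The labels do not say whether replicate numbers pair the samples, and the values do not settle it. Same-numbered libraries correlated in their deviations at 0.199, -0.0209 and 0.183 in BMSC and at 0.0140, 0.0196 and -0.00285 in BF. BMSC-C replicates 1 and 3 correlated best with their own number, but not every library did. Deviations within a group cancel out and carry the length trend, so they neither show nor exclude pairing. With the replicate number as a block, limma called 3003 genes and 6 lists for BMSC-CT, and 0 genes (977 at an unadjusted p under 0.05) and 8 lists for BF-D. The median docetaxel effect on raised genes was 0.0408 with the block (camera p = 0.401 with an estimated correlation).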

Other observations

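The slopes along the treatment direction, both macrophage tests and the splits for genes changed in BF-D were chosen only after the results were seen, while the length tests and other splits were fixed before.

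BMSC-CT replicate 3 stood apart from replicates 1 and 2. Its deviation across genes is in line with a bias for short transcripts (Spearman rho with gene length -0.404, shortest 25% of genes at 1.00 and longest at -0.82). A further move along the treatment direction would give a positive slope, and the slope was 0.231. Those of replicates 1 and 2 were -0.193 and -0.0385, but the slopes of a group cancel out by construction. They are therefore no separate reference. The length trend was not removed before the slopes were taken, so they cannot tell such a move from the length bias. A larger share of macrophages stays open, because with the length trend removed the macrophage list exceeded the higher of the fibrous matrix and mesenchymal stem cell lists by 0.129. A difference in RNA quality may explain the length trend, but RNA integrity values were not analysed here.

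BF-D replicate 2 stood apart from replicates 1 and 3, with a rho with gene length of -0.356 that is in line with a bias for short transcripts. A stronger response to docetaxel stays open, with a slope of 0.0338. The slopes of replicates 1 and 3, 0.0102 and -0.0440, are no separate reference, because the slopes of a group cancel out by construction. The calls that appear without this library, 245 against 2, may reflect the smaller spread of the libraries that remain, and 264 were called when the length trend was also removed. Those 245 calls rest on 5 libraries, and 2 of these are treated.

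Many lysosome genes and some macrophage genes rose in BMSC-CT. A larger share of unchanged macrophages is argued against by 8 macrophage genes that fell without BMSC-CT replicate 3, beside 8 that rose. Over all 6 libraries 6 rose and 2 fell by limma, which does not decide the question. A change in the state of the macrophages, alone or with a change in their share, stays open, since bulk RNA cannot separate them from the stromal cells.

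Each 6 libraries can be split into 3 and 3 in 10 ways, so no share under 0.05 is possible. For genes changed, 1 of 10 splits, the real one, gave as many in BMSC-CT (3134, highest other 0) and 1 of 10 in BF-D (2, highest other 1). For gene lists it was 1 of 10 in BMSC-CT (6, highest other 4) and 1 of 10 in BF-D (8, highest other 5). For the median docetaxel effect on genes raised by CTGF and TGF-beta1, 6 of 10 splits lay as far from 0 as the real 0.0408 (highest other 0.0501).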
